A study of Mus with 15 samples.

How the data were processed

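Bulk RNA was measured in 15 libraries of sorted mouse thymocytes, 3 for each of 5 gates, with a stranded total RNA kit (SMARTer Stranded Total RNA-Seq Pico v2) after mechanical dissociation, magnetic depletion of CD8-positive cells and flow sorting, per the labels' protocols. The replicates are biological replicates of 1 sort experiment, per the labels, which do not state whether a replicate is a mouse or a pool of mice, so p-values describe the spread between these samples. The deposited values are raw counts of read pairs per gene for 55573 Ensembl genes. The counts were made with featureCounts 1.6.2 on the Ensembl 97 annotation of GRCm38, with both ends mapped, a mapping quality of at least 10 and reverse-strand counting (strand setting 2), per the file headers. Trimming with Trimmomatic 0.33, alignment with HISAT2 2.1.0 and featureCounts 1.4.6 are named per the submitters' processing notes, which differ from the header in the counter's version. Each of the 15 value columns was mapped to 1 library, and 0 entries of the table named no gene. Counts of molecules cannot be told from copies made by amplification, so counting intervals and floors cover counting error only.

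The count table gives no symbols. Genes were named by matching positions to a RefSeq table of the same build (GRCm38.p6), with a Jaccard overlap of at least 0.5 and a margin of 0.2 to the next partner, or a shared end (322 genes) or a sole partner (1029 genes) at a lower overlap. This named 35426 genes, while 11865 had a best overlap under the minimum and 731 were ambiguous. Unnamed genes were tested but are not named in the text. Of 507 entries in 22 gene lists, 492 were matched. The 15 without a match were Tigit, Ifi27l2a, Cd52, Slfn2, Crip1, Ube2c, Ccl4, Gpr55, Ahsp, Junb, Dusp1, Hspa1a, Hspa8 and Maf, which stood in a pair of lists.

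Differential expression was tested in R 4.3.3 with edgeR 4.0.16, by the quasi-likelihood test (robust) on counts of all 15 libraries with 5 group means, after the default filter on low counts (filterByExpr) and TMM normalization, which left 16069 genes. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, with no fold threshold. The comparisons were the 6 pairs among conventional CD4SP cells, CD25+ progenitors, FOXP3lo progenitors and mature Tregs, Bst2+ cells against the average of the 3 other gates with CD25 or FOXP3, and the interaction of CD25 and FOXP3 gates. CPM values were computed from the counts and TMM factors. A fold against a group with no count is a bound against a floor of 3 counts over the group. With 1 to 3 counts the ratio is given with its 95% counting interval.

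The gene lists, the comparisons, the alternatives and the rule for named genes were fixed before the data were examined. The lists cover the Treg signature, TCR-induced genes, NF-κB and TNF receptors, IL-2 and STAT5 targets, interferon-stimulated genes, immature thymocytes, mature single-positive thymocytes, chemokine receptors and homing, apoptosis regulators, proliferation, effector helper T cells, recirculating Tregs, NKT and innate-like T cells, gamma-delta T cells, CD8 and double-positive cells, B cells, plasmacytoid dendritic cells, dendritic cells and macrophages, thymic epithelium and stroma, erythroid cells, dissociation and immediate early genes, and mitochondrial encoded genes. Lists can share members, and gate genes belong to none. Lists with at least 5 tested members (21 lists) were tested in 7 comparisons with limma 3.58.1 (camera, preset correlation of 0.01, log2 CPM with a prior count of 2), adjusted over the 147 tests, and again with an estimated correlation and with fry. Named genes are, per comparison, the 8 highest and 8 lowest fold changes among called genes whose libraries do not overlap (chance gives 10% for 3 against 3) with a mean of at least 5 CPM in the higher group, leaving out gate genes, antigen receptor segments, pseudogenes, small RNAs and clone names. Up to 3 called members per list with the smallest adjusted p and the gate genes were added, and for the interaction the 4 highest and 4 lowest without the overlap condition. The position between conventional cells and mature Tregs was compared with an exact two-sided permutation test, whose smallest p is 0.1 for 3 against 3.

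Replicate numbers were taken to mark shared biological replicates, from the design. Deviations from the group means of same-numbered libraries had correlations across genes of −0.02 to 0.04 (mean 0.0107, 30 pairs), and those of other pairs −0.04 to 0.03 (mean −0.00535, 60 pairs), genes not being independent replicates. No library was a duplicate of another by the spread of its counts around its replicates.

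Alternatives were RLE and upper quartile factors, no filter on low counts, a filter of 2 CPM in 3 libraries, the replicate number as a block, a test against a fold of 1.5, the 20 most abundant genes left out, a fit of only the groups compared, limma-voom, DESeq2 1.42.0, leaving out each library in turn, mature Tregs alone or conventional cells as the reference for Bst2+ cells, a fold over 4 and a prior count of 0.5. A fit without the Bst2+ libraries was added after seeing the data. The overlap of progenitor comparisons that share controls was set against 20 simulations of unchanged groups. Further lists were written for the closing tests after the first results were seen. They cover macrophages, neutrophils, pan T cells, double-negative and double-positive thymocytes, ribosome biogenesis and endoplasmic reticulum chaperones. Python 3.11.15, NumPy 2.4.6 and matplotlib 3.10.9 were used for tables and plots.

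The steps were tested on simulated counts for 16069 genes with 100 genes changed 2-fold and 100 changed 4-fold per comparison. Of these, 33 and 55 were recovered for CD25+ progenitors against conventional cells (5 false calls among 15869 unchanged genes), 27 and 59 for FOXP3lo progenitors (6), 27 and 63 for mature Tregs (2), 25 and 49 between the progenitors (4), 37 and 50 for mature Tregs against CD25+ progenitors (2), 31 and 55 for mature Tregs against FOXP3lo progenitors (4), 45 and 59 for Bst2+ cells (7) and 18 and 49 for the interaction (9). Simulated lists of 25 genes moved by 1.5-fold were found in 8 of 8 comparisons and unmoved lists in 0 of 8. A gene that was not called may therefore have changed by 2-fold or more. Each simulated library took 1 spread per gene pooled over all 15 libraries (biological coefficient of variation 0.42). The spread was 0.937 among the Bst2+ libraries and 0.149 to 0.24 within the other gates, so recovery and false calls may differ from those given.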

Results

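RNA from sorted mouse thymocytes was measured by bulk sequencing. The cells came from 6-week-old female mice of a C57Bl/6 background carrying Foxp3-GFP. Each gate took live cells with the T cell receptor (TCR) beta chain and CD4 on their surface, without CD8 and without CD73, an ecto-enzyme. Within these, 5 gates were set on CD25 (the alpha chain of the IL-2 receptor), FOXP3 (the transcription factor that defines regulatory T cells, Tregs) and BST2 (a membrane protein induced by interferon). Conventional CD4 single-positive (CD4SP) cells had neither CD25 nor FOXP3, CD25+ progenitors had CD25 alone, FOXP3lo progenitors had low FOXP3 alone, and mature Tregs had both. These 4 gates excluded BST2, while the Bst2+ gate took BST2-positive cells with CD25, FOXP3 or both. Each gate was represented by 3 libraries, numbered 40, 42 and 43, from 3 biological replicates of 1 sort experiment. The libraries held between 10816064 and 23758157 assigned counts. Their group means were 1.775e+07 ± 5.539e+06 counts for conventional cells, 1.756e+07 ± 1.861e+06 for CD25+ progenitors, 1.844e+07 ± 2.399e+05 for FOXP3lo progenitors, 1.446e+07 ± 1.65e+06 for mature Tregs and 1.312e+07 ± 2.406e+06 for Bst2+ cells (SD, n = 3). In what follows, levels are CPM (counts scaled to a common library size, the standard edgeR unit) as mean ± SD of 3 libraries, log2 fold changes are given ± standard error, and coordinates refer to GRCm38. Adjusted p-values for genes are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over 16069 genes.

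The gate genes followed the sort for FOXP3 and CD25. Foxp3 (ENSMUSG00000039521, chromosome X, 7573644 to 7595245) averaged 0.951 ± 0.545 CPM in conventional cells, 3.202 ± 1.24 in CD25+ progenitors, 290.0 ± 15.9 in FOXP3lo progenitors and 598 ± 59.7 in mature Tregs. The difference between mature Tregs and FOXP3lo progenitors, a log2 fold change of 1.04 ± 0.32, was not called (adjusted p = 0.0751), and it was called without the Bst2+ libraries and with limma-voom, both at a log2 fold change of 1.05, and with no filter on low counts, at 1.03, a fit that takes no account of the spread of single genes. Foxp3 was higher in CD25+ progenitors than in conventional cells by 1.81 ± 0.56 (adjusted p = 0.0428). This call was lost with the replicate number as a block and with limma-voom, both at 1.79, and without conventional replicate 40 or 43, at 1.67 and 1.55, or CD25+ progenitor replicate 40 or 43, at 1.59 and 1.70. Il2ra, which encodes CD25 (ENSMUSG00000026770, chromosome 2, 11642807 to 11693193), averaged 9.07 ± 1.47 CPM in conventional cells, 107 ± 9.12 in FOXP3lo progenitors, 289 ± 6.84 in CD25+ progenitors and 1152 ± 29.3 in mature Tregs. The FOXP3lo gate excluded surface CD25, yet Il2ra was higher there than in conventional cells by 3.55 ± 0.19 on the log2 scale (adjusted p = 3.06e-09). Bst2 (ENSMUSG00000046718, chromosome 8, 71534255 to 71537456) lay between 12.2 and 15.1 CPM on average in the 4 gates that excluded the protein. In the Bst2+ gate it was at 50.3, 18.4 and 15.7 CPM in replicates 40, 42 and 43. Its log2 fold change over the other CD25 or FOXP3 gates, 1.03 ± 0.27 (adjusted p = 0.00697), fell short of the threshold without Bst2+ replicate 40, at 0.31. In the same Bst2+ libraries Foxp3 was at 9.10, 28.1 and 40.2 CPM and Il2ra at 261.1, 307.8 and 163.2 CPM. Cd4 averaged between 531 CPM in mature Tregs and 859 in conventional cells. Cd8a averaged between 2.46 CPM in FOXP3lo progenitors and 21.5 in Bst2+ cells, Trbc1 between 132 and 241, and Trbc2 between 191 and 298. Nt5e, which encodes CD73, was at most 11.4 ± 1.89 CPM on average, in mature Tregs.

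**Figure D1:**
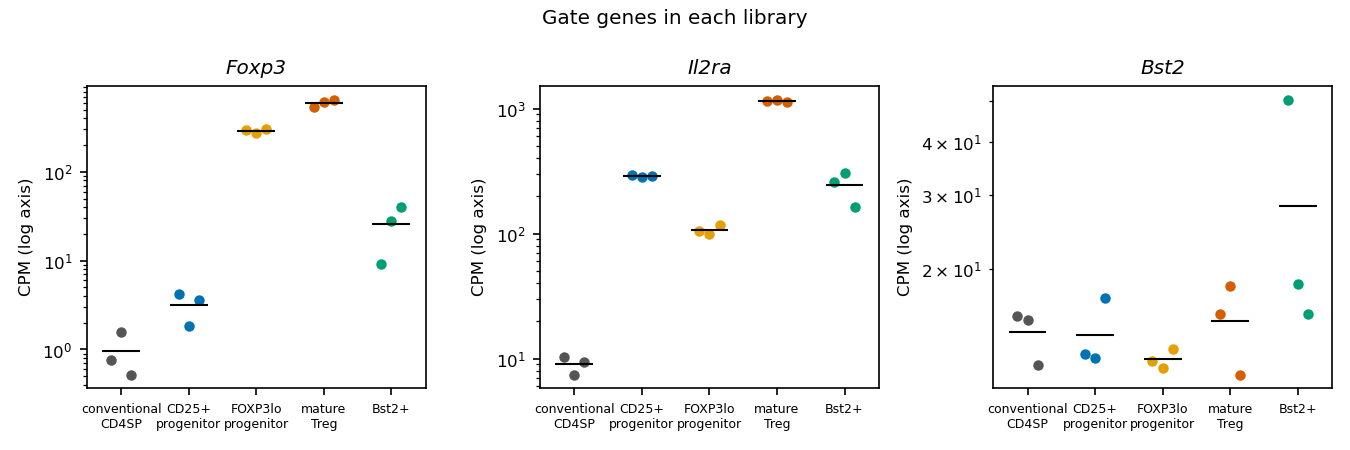
CPM (log axis) of Foxp3, Il2ra and Bst2 in each of the 15 libraries, with points for libraries and lines for group means of 3 libraries. Foxp3 averages 290 CPM in FOXP3lo progenitors and 598 in mature Tregs against 0.951 in conventional cells, while Bst2 in the Bst2+ gate spans 15.7 to 50.3 CPM.

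The Bst2+ libraries stood apart from the other 12 and from each other. They had the fewest genes with a count, 14685 to 17198 against 18355 to 23382. On the first principal component (37.25% of the variance of log2 CPM) they lay at 124.2, 132.5 and 190 against −56.64 to −15.15 elsewhere. On the second (15.06%) Bst2+ replicate 40 lay at 136.7 and replicates 42 and 43 at −84.88 and −88.85. The biological coefficient of variation was 0.937 among the Bst2+ libraries, 0.149 to 0.24 within the other gates and 0.42 over all 15. Correlations between replicates across genes (log2 CPM, genes not being independent replicates) ran from 0.829 to 0.856 in the Bst2+ gate and from 0.956 to 0.975 in the others. Mitochondrial ribosomal RNA took 17.5% ± 3.01 of the counts in Bst2+ libraries and between 9.73% and 10.7% on average elsewhere. As all libraries share 1 estimate of spread, counts of called genes among the other 4 gates are also given without the Bst2+ libraries, an alternative chosen after seeing the data. That shared estimate lies below the spread among the Bst2+ libraries, so p-values for the Bst2+ gate may be too small.

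**Figure D2:**
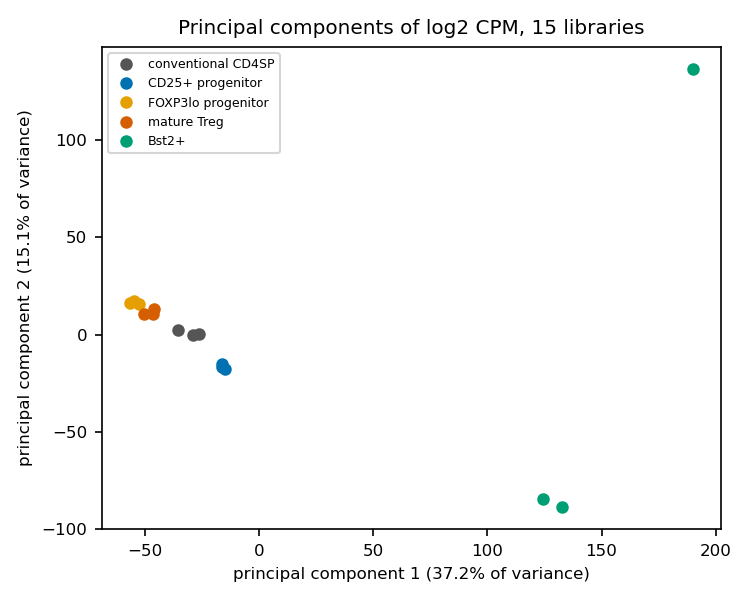
First and second principal components of log2 CPM over the 15 libraries, in arbitrary units, with the share of variance on each axis and points coloured by gate. The 3 Bst2+ libraries lie at 124.2 to 190 on the first component and the remaining 12 between −56.64 and −15.15.

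Conventional CD4SP cells were compared with CD25+ progenitors to see what cells with CD25 but without FOXP3 express. CD25+ progenitors had higher levels of genes induced by TCR signalling, of Treg signature genes and of NF-κB genes, and lower levels of interferon-stimulated genes and of genes that mark late single-positive thymocytes. Ikzf2, which encodes the Treg transcription factor Helios (ENSMUSG00000025997, chromosome 1, 69531214 to 69687245), averaged 1158 ± 48.7 CPM against 95.3 ± 2.79 in conventional cells, a log2 fold change of 3.60 ± 0.15 (adjusted p = 3.07e-10). Tnfrsf9, the costimulatory receptor 4-1BB (ENSMUSG00000028965, chromosome 4, 150914562 to 150946102), averaged 423 ± 48.95 against 36.6 ± 7.81 (3.53 ± 0.17, adjusted p = 8.40e-10). S1pr1, the sphingosine-1-phosphate receptor that T cells need to leave the thymus (ENSMUSG00000045092, chromosome 3, 115710433 to 115715072), averaged 75.8 ± 9.41 against 199.8 ± 21.8 (−1.40 ± 0.10, adjusted p = 8.49e-08).

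Of 26 Treg signature genes tested in CD25+ progenitors against conventional cells, 13 rose and 3 fell (15 and 3 adjusted over the list alone), with a median log2 fold change of 1.74, or 1.42 with the member at 0 in 1 group at its bound. Swap70, a GTPase-binding adaptor, rose by 2.22 ± 0.10. TCR-induced genes rose in 16 of 25 cases and fell in 5 (also 16 and 5 adjusted over the list alone, median 1.34), among them Nr4a3, an immediate TCR-response nuclear receptor (1.89 ± 0.10), and Tagap (2.38 ± 0.19). NF-κB and TNF receptor genes rose in 14 of 25 cases and fell in 2 (15 and 2 adjusted over the list alone), with Tnfrsf4, which encodes OX40, at 190.1 ± 38.3 CPM against 39.9 ± 6.03 and Tnfrsf1b, which encodes TNFR2, at 228 ± 31.3 against 54.8 ± 3.76. Interferon-stimulated genes fell in 25 of 58 cases and rose in 0 (36 and 0 adjusted over the list alone, median −0.72), for example Ifi213 (−2.08 ± 0.21) and Ddx58, which encodes the RNA sensor RIG-I (−1.06 ± 0.11). Mature single-positive genes fell in 16 of 26 cases (18 lower and 1 higher adjusted over the list alone, median −0.84), with Gimap3 (−1.64 ± 0.08), Ms4a6b (−1.74 ± 0.12) and S1pr1 among them. Effector helper genes rose in 9 of 18 (9 adjusted over the list alone), including Rora, an orphan nuclear receptor (123 ± 7.48 CPM against 26.6 ± 5.19), Bcl6 (1.58 ± 0.20) and Tnfsf8 (1.44 ± 0.18). The IL-2 and STAT5 list was split, 7 members higher and 7 lower of 24 (8 and 8 adjusted over the list alone), with Cish, a STAT5-induced feedback inhibitor, higher (2.31 ± 0.26) and Bcl2 lower (−0.90 ± 0.08). Without the Bst2+ libraries the higher and lower members numbered 15 and 3 for the Treg signature, 18 and 6 for TCR-induced, 20 and 3 for NF-κB, 0 and 49 for interferon and 1 and 22 for mature single-positive genes. In that fit they were 10 and 2 for effector helper and 9 and 9 for IL-2 and STAT5 genes.

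Some transcripts of other thymocyte and T cell stages were also higher in the CD25+ progenitor libraries than in conventional cells. Rag1, part of the recombinase that assembles antigen receptor genes (ENSMUSG00000061311, chromosome 2, 101638282 to 101649501), averaged 57.9 ± 15.9 CPM against 2.56 ± 3.07 (4.65 ± 0.50, adjusted p = 6.01e-06), Dntt, the terminal transferase, 76.5 ± 14.7 against 25.1 ± 3.87, and Cd24a, lost as thymocytes mature, 101 ± 7.67 against 28.7 ± 4.97. The gamma-delta T cell list had 5 of 9 members higher and 0 lower (5 and 0 adjusted over the list alone), with Trgc2 at 15.1 ± 1.85 CPM against 0.119 ± 0.158. The Trgc genes are near-identical copies among which reads are uncertain. Its median log2 fold change was 3.77, or 2.85 with members at 0 at their bound, and its camera call was lost with an estimated correlation (adjusted p = 8.08e-05 preset, adjusted p = 0.0692 with an estimated correlation). The CD8 and double-positive list had 6 of 11 higher (6 adjusted over the list alone, adjusted p = 0.001999, or adjusted p = 0.0498 with an estimated correlation), a call lost with an estimated correlation without the Bst2+ libraries (adjusted p = 0.123). The immature thymocyte list went both ways, 8 higher and 6 lower of 25 (adjusted over the list alone as well), the lower ones including the chromatin organiser Satb1 (−1.10 ± 0.09) and Lef1 (−1.02 ± 0.08), and was not called (adjusted p = 0.375). Of 29 proliferation genes, 4 rose, all subunits of the DNA replication helicase such as Mcm6 (1.04 ± 0.17), and the list was not called (adjusted p = 0.954). Leaving out the Bst2+ libraries, the higher and lower members were 5 and 0 for gamma-delta, 6 and 2 for CD8 and double-positive, 9 and 11 for immature and 4 and 1 for proliferation genes.

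In total 1871 genes were called, 961 higher and 910 lower (427 and 259 by over 2-fold), 4534 without the Bst2+ libraries (2302 higher and 2232 lower), 4623 with only the compared groups fitted, and 464 in a test against a fold of 1.5. Of the genes named above, that last test no longer called Foxp3 and Mcm6. Camera adjusted p-values were 6.91e-10 for the Treg signature, 2.31e-10 for TCR-induced, 3.69e-10 for NF-κB, 4.21e-18 for interferon, 3.60e-18 for mature single-positive and 1.82e-05 for effector helper genes, and these 6 calls held with an estimated correlation. The interferon call was lost with an estimated correlation in the fit without the Bst2+ libraries (adjusted p = 0.05502). Outside the lists, H19, an imprinted non-coding RNA of proliferating fetal and progenitor cells (ENSMUSG00000000031, chromosome 7, 142575529 to 142578143), averaged 11.7 ± 3.14 CPM against a single count in conventional cells, a ratio of 637 (95% counting interval 114 to 25220). Gfra1 had no count in conventional cells and was at least 95.4-fold higher (floor of 3 counts over the group). Wnt10a, Xcl1, Epb41l4b and Bcat1 rose by 7.02, 6.92, 6.13 and 5.93 on the log2 scale. Genes that fell included Appl2 (−3.29 ± 0.33), Ggt5 (−2.90 ± 0.39), Rflnb (−2.83 ± 0.49) and Hs3st3b1 (−2.66 ± 0.43).

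FOXP3lo progenitors differed from conventional cells in the same Treg, TCR and NF-κB lists, and in the opposite direction to CD25+ progenitors for interferon-stimulated and late-maturation genes. FOXP3lo progenitors had less of the cell cycle program than conventional cells. Ikzf2 averaged 596 ± 53.3 CPM (2.64 ± 0.15, adjusted p = 5.69e-09), S1pr1 616 ± 4.496 (1.62 ± 0.10, adjusted p = 2.00e-08) and Top2a, the topoisomerase of dividing cells, 50.2 ± 3.93 against 182 ± 13.3 (−1.86 ± 0.15, adjusted p = 2.70e-07). Ctla4, an inhibitory receptor of Tregs, averaged 90.1 ± 5.79 against 11.2 ± 1.12 (3.01 ± 0.24, adjusted p = 2.91e-07). Il7r, the IL-7 receptor alpha chain (ENSMUSG00000003882, chromosome 15, 9505788 to 9530176), averaged 45.6 ± 6.01 against 344 ± 18.1 (−2.91 ± 0.21, adjusted p = 8.53e-08).

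Of 26 Treg signature genes, 15 rose and 1 fell in FOXP3lo progenitors (16 and 1 adjusted over the list alone, median 1.52, 1.39 with members at 0 at their bound). TCR-induced genes rose in 12 of 25 and fell in 3 (13 and 3 adjusted over the list alone), with Cblb, a ubiquitin ligase that restrains TCR signalling (1.29 ± 0.09), Nr4a3 (1.13 ± 0.10) and Tnfrsf9 (1.90 ± 0.16). NF-κB genes rose in 14 of 25 (18 adjusted over the list alone), among them Rel, the c-Rel subunit (0.99 ± 0.10). Interferon-stimulated genes rose in 23 of 58 and fell in 1 (32 and 1 adjusted over the list alone, median 0.53), with Ifi209 (0.95 ± 0.09) and Ifi206 (1.00 ± 0.12) as examples. Mature single-positive genes rose in 17 of 26 (17 higher and 3 lower adjusted over the list alone), with Gimap3 at 684 ± 27.4 CPM against 334 ± 22.8. The member that fell was Il7r. Proliferation genes fell in 20 of 29 (26 adjusted over the list alone, median −1.54), including Mki67 (−1.68 ± 0.17) and Kif11 (−2.08 ± 0.23). Without the Bst2+ libraries the higher and lower members were 17 and 1 for the Treg signature, 17 and 3 for TCR-induced, 21 and 0 for NF-κB, 39 and 2 for interferon, 19 and 3 for mature single-positive and 0 and 27 for proliferation genes. That fit gave 3 and 14 for immature, 1 and 5 for CD8 and double-positive and 9 and 3 for IL-2 and STAT5 genes.

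Smaller groups also moved in FOXP3lo progenitors. Immature thymocyte genes fell in 11 of 25 and rose in 1 (14 and 3 adjusted over the list alone), with Itm2a (−1.66 ± 0.13) lower and Myb, a transcription factor of early thymocytes, higher (1.55 ± 0.17), and the call was lost with an estimated correlation (adjusted p = 0.0592 with an estimated correlation). CD8 and double-positive genes fell in 4 of 11 (5 lower and 1 higher adjusted over the list alone), with Runx3 (−1.87 ± 0.19) and Dntt (−2.44 ± 0.27), at adjusted p = 0.0151, which became adjusted p = 0.101 with an estimated correlation and 0.0799 without conventional replicate 42. The IL-2 and STAT5 list had 7 of 24 higher and 1, Id2, lower (9 and 3 adjusted over the list alone), with Il2rb, the IL-2 receptor beta chain, at 183 ± 17.1 CPM against 24.1 ± 5.92, and adjusted p = 0.0274 or adjusted p = 0.119 with an estimated correlation.

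In total 1400 genes were called, 784 higher and 616 lower (273 and 281 by over 2-fold), 3925 without the Bst2+ libraries (2003 higher and 1922 lower), 4459 with only the compared groups fitted, and 336 in a test against a fold of 1.5. By camera, adjusted p-values were 2.01e-16 for the Treg signature, 4.76e-09 for TCR-induced, 9.70e-16 for NF-κB, 3.20e-15 for interferon, 2.10e-13 for mature single-positive and 2.28e-26 for proliferation genes, and these 6 calls held with an estimated correlation. The interferon call was lost with an estimated correlation when the Bst2+ libraries were left out (adjusted p = 0.07997). The genes that rose most included Flicr, a non-coding RNA next to Foxp3 (6.17 ± 0.96), Coro2a (5.20 ± 0.38), Itgb8 (5.96 ± 0.98) and Penk, which encodes the opioid precursor proenkephalin (4.34 ± 0.56), and those that fell most included Aqp9 (−4.64 ± 0.77), the IL-25 receptor gene Il17rb (−4.47 ± 0.36) and Asb2 (−4.27 ± 0.80). The number of called genes was 865, 879 and 852 without FOXP3lo progenitor replicate 40, 42 or 43 and 853 and 812 without conventional replicate 42 or 43, fits that have 1 library fewer.

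Both progenitor comparisons share the conventional libraries. Genes higher in both numbered 238, against 46.9 for independent lists of these sizes, and genes lower in both 113 against 34.9. Genes higher in CD25+ but lower in FOXP3lo progenitors numbered 103 (36.8 for independent lists), and the reverse 154 (44.4). Unchanged groups simulated against the same controls gave 0 in each class over 20 simulations. The fold changes had a Pearson r of 0.359 across the 16069 genes, where simulated unchanged groups gave 0.504 (0.482 to 0.519), and a covariance of 0.403 against a simulated 0.338 (0.318 to 0.35), a difference of 0.0655. Fold changes had the same sign for 54.4% of genes and for 66.8% in the simulations. The simulations took the spread of all 15 libraries, a biological coefficient of variation of 0.42. It was 0.164 in conventional cells, 0.2 in CD25+ and 0.149 in FOXP3lo progenitors. The simulated r, covariance and share of equal signs may thus overstate what shared controls give, and no conclusion is drawn from them. With 3 control libraries no split could leave 2 on each side, so part of any excess may come from the shared controls.

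Mature Tregs were compared with conventional cells as the gate with both CD25 and FOXP3. They had more Treg signature, NF-κB, IL-2 response and late-maturation transcripts, and fewer cell cycle transcripts. Swap70 averaged 269 ± 6.53 CPM against 35.96 ± 1.101 (2.90 ± 0.11, adjusted p = 2.69e-11). Lrrc32, which encodes GARP, the TGF-β docking receptor of Tregs (ENSMUSG00000090958, chromosome 7, 98489283 to 98502181), averaged 286 ± 7.21 against 1.597 ± 0.165 (7.50 ± 0.40, adjusted p = 9.32e-10). Coro2a, a coronin of the actin cytoskeleton (ENSMUSG00000028337, chromosome 4, 46536937 to 46602202), averaged 115 ± 8.33 against 0.3004 ± 0.134 (8.46 ± 0.39, adjusted p = 2.39e-10). Ctla4 averaged 200.3 ± 18.8 CPM (4.16 ± 0.25, adjusted p = 3.83e-09). Cd40lg, the CD40 ligand of helper T cells (ENSMUSG00000031132, chromosome X, 57212143 to 57224042), averaged 14.4 ± 0.484 against 105 ± 7.57 (−2.86 ± 0.14, adjusted p = 6.37e-10).

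In mature Tregs, 20 of 26 Treg signature genes rose and 0 fell (20 and 1 adjusted over the list alone, median 3.06), including Tnfrsf4 at 371 ± 22.2 CPM. NF-κB genes rose in 18 of 25 (21 adjusted over the list alone), with Rel (1.94 ± 0.10) and Tnfrsf18, which encodes GITR (2.48 ± 0.15). IL-2 and STAT5 genes rose in 14 of 24 and fell in 2 (15 and 3 adjusted over the list alone). Id2, an inhibitor of helix-loop-helix factors, was among those that fell (−3.92 ± 0.23). TCR-induced genes rose in 10 and fell in 5 of 25 (11 and 5 adjusted over the list alone), with Cd83 (5.95 ± 0.43) and Nr4a3 (1.53 ± 0.10) higher. Mature single-positive genes rose in 17 of 26 and fell in 1, Il7r (19 and 2 adjusted over the list alone). Apoptosis regulators rose in 9 of 24 and fell in 1 (13 and 2 adjusted over the list alone), with the survival factor Mcl1 (0.77 ± 0.07). Proliferation genes fell in 17 of 29 (24 adjusted over the list alone, median −1.49), including Birc5 (−2.78 ± 0.29). Immature thymocyte genes fell in 10 and rose in 1 of 25 (12 and 1 adjusted over the list alone), with Satb1 (−1.49 ± 0.09) and Itm2a (−1.95 ± 0.13). Without the Bst2+ libraries the higher and lower members were 21 and 2 for the Treg signature, 22 and 0 for NF-κB, 16 and 4 for IL-2 and STAT5, 19 and 3 for mature single-positive and 1 and 23 for proliferation genes. They were 14 and 6 for TCR-induced, 14 and 2 for apoptosis, 2 and 14 for immature, 30 and 4 for interferon and 12 and 6 for chemokine and homing genes.

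In total 1957 genes were called, 1037 higher and 920 lower (482 and 426 by over 2-fold), 4756 without the Bst2+ libraries (2369 higher and 2387 lower), 4418 with only the compared groups fitted, and 628 in a test against a fold of 1.5. Camera adjusted p-values were 5.94e-26 for the Treg signature, 1.05e-18 for NF-κB, 1.15e-07 for IL-2 and STAT5, 3.94e-05 for TCR-induced, 1.40e-11 for mature single-positive, 4.10e-05 for apoptosis, 6.77e-06 for immature and 8.24e-17 for proliferation genes, and these 8 calls held with an estimated correlation, narrowly for TCR-induced and immature genes (adjusted p = 0.0498 and 0.0498). Both were lost when the Bst2+ libraries were also left out (adjusted p = 0.05005 and 0.114). Interferon-stimulated genes were 13 higher and 2 lower of 58 (22 and 2 adjusted over the list alone), at adjusted p = 1.47e-04 and adjusted p = 0.163 with an estimated correlation. Chemokine and homing genes were 10 higher and 3 lower of 22 (11 and 3 adjusted over the list alone), with Ccr4 lower (−3.50 ± 0.40), at adjusted p = 0.0213, which became 0.0692 with an estimated correlation and 0.0571 without mature Treg replicate 40. Of the 8 genes with the strongest decreases, Pdlim4 had no count in mature Tregs and was at least 95.5-fold lower, and Asb2, Pxylp1, Appl2 and Chl1 fell by 6.44, 6.21, 5.64 and 5.36 on the log2 scale.

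CD25+ progenitors were compared directly with FOXP3lo progenitors, the other Treg progenitor gate. FOXP3lo progenitors had more interferon-stimulated and late-maturation transcripts, and CD25+ progenitors more of the cell cycle and effector transcripts. S1pr1 had a log2 fold change of −3.02 ± 0.11 in CD25+ over FOXP3lo progenitors (adjusted p = 1.40e-11) and Gimap3 −2.67 ± 0.08 (adjusted p = 2.53e-12). Ifi203, an interferon-inducible gene of the DNA-sensor family, averaged 67.1 ± 5.23 CPM against 261 ± 8.76 (−1.96 ± 0.12, adjusted p = 9.54e-09). Bcl2l1, which encodes the survival protein BCL-XL (ENSMUSG00000007659, chromosome 2, 152780668 to 152831728), averaged 138 ± 5.67 against 35.5 ± 3.64 (1.96 ± 0.12, adjusted p = 4.20e-09).

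Between the progenitors, 46 of 58 interferon-stimulated genes were lower in CD25+ cells and 0 higher (51 and 0 adjusted over the list alone, median −1.32), among them Ifi209 (−1.75 ± 0.10) and Rnf213 (−1.47 ± 0.09). Mature single-positive genes were lower in 23 of 26 (23 adjusted over the list alone, median −1.42). Proliferation genes were higher in 21 of 29 (25 adjusted over the list alone, median 1.55), with the replication helicase genes Mcm5 (1.70 ± 0.14) and Mcm3 (1.58 ± 0.14). Effector helper genes were higher in 8 of 18 (10 adjusted over the list alone), with Cd40lg (1.35 ± 0.13) and Rora (1.95 ± 0.23). CD8 and double-positive genes were higher in 7 of 11 (7 adjusted over the list alone) and gamma-delta genes in 5 of 9 (6 adjusted over the list alone), with Dntt (4.05 ± 0.28), Rag1 (4.68 ± 0.50) and Trgc2 (5.92 ± 0.56). Immature thymocyte genes were higher in 12 and lower in 3 of 25 (12 and 4 adjusted over the list alone), with Cd24a (2.83 ± 0.17) and Arpp21 (3.46 ± 0.33), at adjusted p = 8.19e-05, or adjusted p = 0.0763 with an estimated correlation. The recirculating Treg list (4 of 11 higher, adjusted p = 0.0326) and the NKT and innate-like list (4 of 9, adjusted p = 0.0327), with the same counts adjusted over the list alone, lost their calls with an estimated correlation (adjusted p = 0.119 and 0.111). The recirculating list also lost it without CD25+ replicate 40 or 43 or FOXP3lo replicate 42 (0.0602, 0.0523 and 0.0502). The NKT list lost it without CD25+ replicate 40, 42 or 43 (0.184, 0.095 and 0.153) or FOXP3lo replicate 40, 42 or 43 (0.115, 0.148 and 0.0865). The Treg signature (7 higher, 5 lower of 26), with Tnfrsf9 higher (1.64 ± 0.16) and Gpr83 lower (−1.69 ± 0.15), was not called, nor were TCR-induced genes (10 and 7 of 25), with Irf4 higher (2.41 ± 0.20). The same was true of NF-κB genes (6 and 4), with Traf1 lower (−1.48 ± 0.12), and IL-2 and STAT5 genes (3 and 7). Adjusted over the list alone these were 7 and 6, 12 and 7, 6 and 4, and 3 and 8.

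In total 3069 genes were called, 1595 higher and 1474 lower (814 and 502 by over 2-fold), 6187 without the Bst2+ libraries (3110 higher and 3077 lower), 6409 with only the compared groups fitted, and 946 in a test against a fold of 1.5. Adjusted p-values by camera were 1.08e-28 for interferon, 9.10e-24 for mature single-positive, 3.41e-17 for proliferation, 3.94e-05 for effector helper, 5.00e-06 for CD8 and double-positive and 5.00e-06 for gamma-delta genes, and these 6 calls held with an estimated correlation. Without the Bst2+ libraries the higher and lower members were 0 and 55 for interferon, 0 and 24 for mature single-positive, 26 and 0 for proliferation, 12 and 1 for effector helper, 10 and 1 for CD8 and double-positive, 7 and 0 for gamma-delta genes. They were 16 and 6 for immature, 5 and 1 for recirculating Treg, 5 and 1 for NKT and innate-like, 8 and 8 for the Treg signature, 13 and 9 for TCR-induced, 8 and 6 for NF-κB and 6 and 10 for IL-2 and STAT5 genes. H19 had no count in FOXP3lo progenitors and was at least 209-fold higher in CD25+ progenitors, Nrgn rose by 4.93 and Epb41l4b by 5.70. Ntn4, Slc28a2b, Sntb1, Neurl3 and Art2b had log2 fold changes of −4.80, −4.27, −4.06, −4.01 and −3.71.

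**Figure D3:**
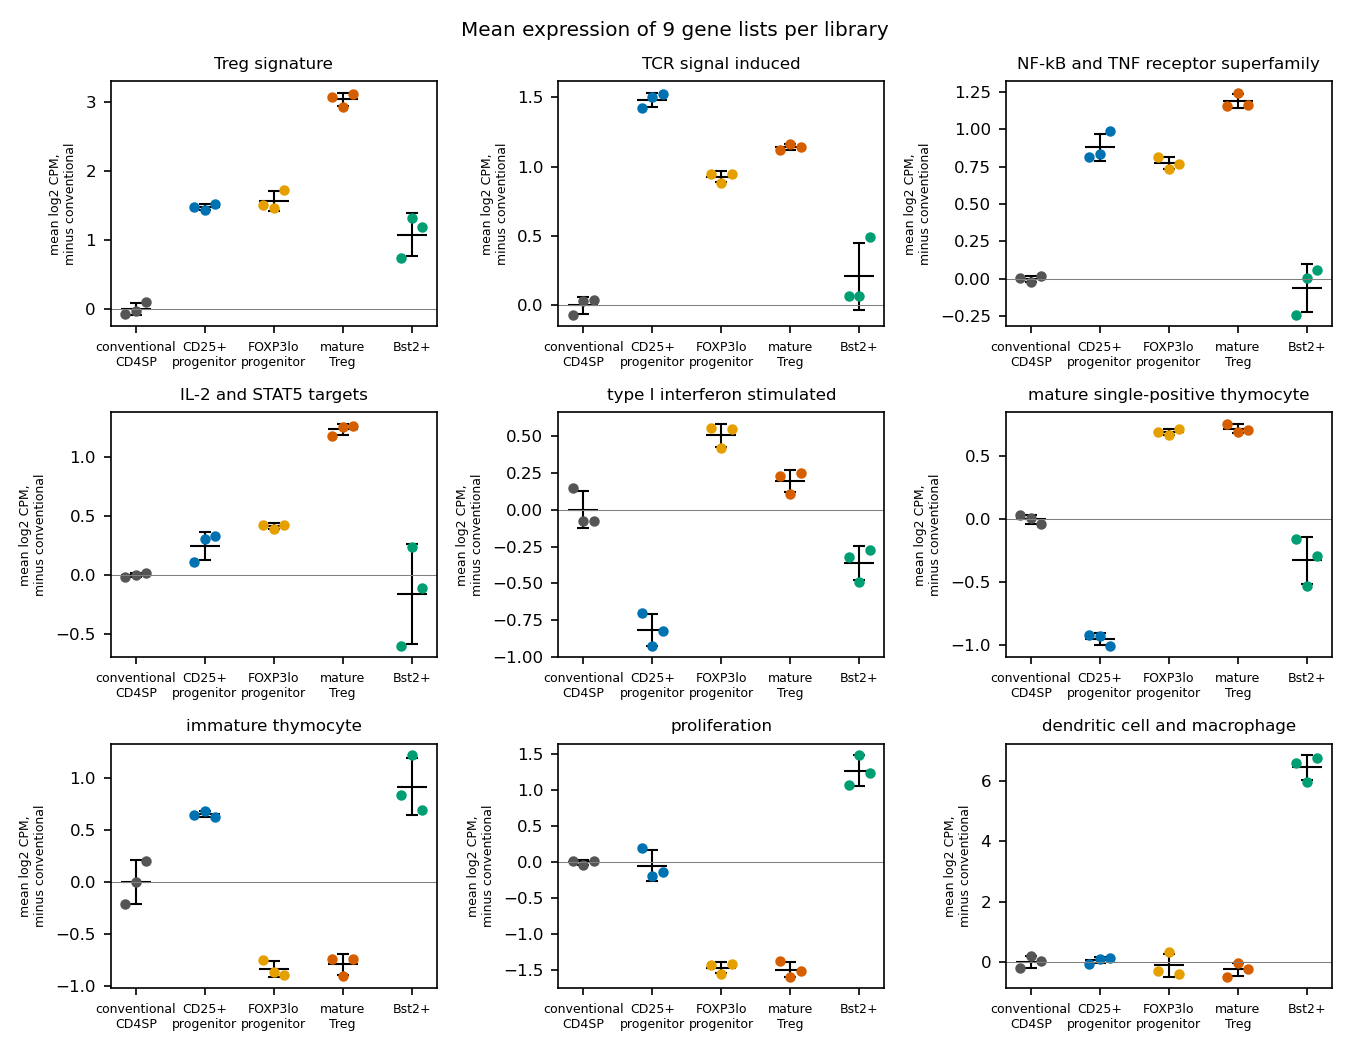
Mean log2 CPM over the tested members of 9 gene lists in each library, minus the mean of the conventional libraries (log2 units), with points for libraries and bars for group means ± SD, n = 3. Interferon-stimulated and mature single-positive lists lie below 0 in CD25+ progenitors and above 0 in FOXP3lo progenitors and mature Tregs, and the dendritic cell and macrophage list stands out in the Bst2+ libraries.

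Mature Tregs against CD25+ progenitors compared the CD25-positive gates with and without FOXP3. Mature Tregs had more Treg signature, IL-2 response, interferon-stimulated and late-maturation transcripts, and fewer cell cycle transcripts. Gpr83, an orphan receptor of the Treg signature (ENSMUSG00000031932, chromosome 9, 14860210 to 14870789), averaged 200.3 ± 11.1 CPM against 12.7 ± 1.92 (3.98 ± 0.16, adjusted p = 8.92e-11). Nrp1, which encodes neuropilin-1, averaged 117 ± 5.19 against 10.01 ± 1.64 (3.54 ± 0.21, adjusted p = 5.52e-09), and Ctla4 had a log2 fold change of 2.85 ± 0.23 (adjusted p = 2.39e-07). Bcl2l11, which encodes the death mediator BIM (ENSMUSG00000027381, chromosome 2, 128126038 to 128162547), averaged 53.8 ± 7.18 against 263 ± 33.1 (−2.29 ± 0.18, adjusted p = 1.95e-07), while Bcl2 averaged 392 ± 11.4 against 164 ± 13.8 (1.26 ± 0.08, adjusted p = 2.23e-08).

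Relative to CD25+ progenitors, 14 of 26 Treg signature genes were higher in mature Tregs and 3 lower (17 and 3 adjusted over the list alone). IL-2 and STAT5 genes were higher in 14 and lower in 2 of 24 (18 and 2 adjusted over the list alone). Interferon-stimulated genes were higher in 38 of 58 (45 adjusted over the list alone, median 0.92) and mature single-positive genes higher in 23 of 26 (24 adjusted over the list alone, median 1.42), with S1pr1 (2.74 ± 0.11). Immature thymocyte genes were lower in 13 and higher in 2 of 25 (14 and 2 adjusted over the list alone), with Sox4 (−1.78 ± 0.10) and Tcf7 (−1.30 ± 0.11) lower. Proliferation genes were lower in 20 of 29 (24 adjusted over the list alone). Effector helper genes were lower in 5 and higher in 1 of 18 (6 and 1 adjusted over the list alone, the higher one being Gata3, 0.98 ± 0.08). Gamma-delta genes were lower in 5 of 9 (8 adjusted over the list alone). CD8 and double-positive genes were lower in 6 of 11 (6 adjusted over the list alone). Chemokine and homing genes were higher in 9 and lower in 5 of 22 (12 and 7 adjusted over the list alone). NF-κB genes were higher in 10 and lower in 2 of 25 (10 and 3 adjusted over the list alone), with Traf1 (1.36 ± 0.12) and Rel (0.98 ± 0.10), at adjusted p = 0.00183, or adjusted p = 0.172 with an estimated correlation. TCR-induced genes were 4 higher and 6 lower of 25 (4 and 8 adjusted over the list alone) and not called (adjusted p = 0.113).

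In total 2096 genes were called, 1090 higher and 1006 lower (385 and 425 by over 2-fold), 5114 without the Bst2+ libraries (2489 higher and 2625 lower), 4687 with only the compared groups fitted, and 510 in a test against a fold of 1.5. The lists had camera adjusted p-values of 3.66e-09 for the Treg signature, 4.69e-08 for IL-2 and STAT5, 2.15e-26 for interferon, 1.66e-30 for mature single-positive, 2.63e-08 for immature, 7.09e-19 for proliferation, 0.0014 for effector helper, 4.83e-06 for gamma-delta, 1.90e-04 for CD8 and double-positive and 0.00727 for chemokine and homing genes, and these 10 calls held with an estimated correlation. In the fit without the Bst2+ libraries an estimated correlation ended the calls of immature (adjusted p = 0.0985), chemokine and homing (0.0809) and effector helper genes (0.05005). Without the Bst2+ libraries the higher and lower members were 17 and 4 for the Treg signature, 19 and 2 for IL-2 and STAT5, 50 and 0 for interferon, 24 and 0 for mature single-positive, 4 and 15 for immature, 0 and 24 for proliferation genes. The same fit gave 1 and 7 for effector helper, 0 and 7 for gamma-delta, 0 and 6 for CD8 and double-positive, 13 and 6 for chemokine and homing, 13 and 4 for NF-κB and 6 and 11 for TCR-induced genes. Ntn4, Flicr, Socs2, a STAT5-induced inhibitor, and Rgs1 rose by 6.71, 5.68, 5.25 and 4.32, and Asb2, Epb41l4b, Nrgn, H19 and Tns3 fell by 5.96, 5.33, 5.26, 5.24 and 4.87 on the log2 scale.

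Mature Tregs and FOXP3lo progenitors, the FOXP3-expressing gates with and without CD25, had the fewest called genes of the 6 pairs. The Treg signature and IL-2 response genes were higher in mature Tregs. Lrrc32 averaged 286 ± 7.21 CPM against 26.02 ± 4.29 (3.46 ± 0.31, adjusted p = 2.93e-06), Gpr83 200.3 ± 11.1 against 41.1 ± 2.66 (2.28 ± 0.15, adjusted p = 1.06e-07), and Tnfrsf4 had a log2 fold change of 1.84 ± 0.16 (adjusted p = 2.22e-06). Cish averaged 203 ± 10.8 against 53.5 ± 1.76 (1.92 ± 0.25, adjusted p = 1.53e-04). Pde3b, a cyclic nucleotide phosphodiesterase (ENSMUSG00000030671, chromosome 7, 114415281 to 114539251), averaged 37.5 ± 8.92 against 302 ± 24.9 (−3.01 ± 0.21, adjusted p = 1.56e-07), and the thymocyte transcription factor gene Tcf7 637 ± 14.1 against 1356 ± 69.1 (−1.09 ± 0.11, adjusted p = 6.97e-06).

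Of 26 Treg signature genes, 14 were higher in mature Tregs than in FOXP3lo progenitors (18 adjusted over the list alone, 19 without the Bst2+ libraries, median 1.16). IL-2 and STAT5 genes were higher in 11 and lower in 4 of 24 (12 and 5 adjusted over the list alone), with the cyclin gene Ccnd2 (0.98 ± 0.09) higher. Apoptosis regulators were higher in 3 and lower in 1 of 24 (4 and 1 adjusted over the list alone), with Bcl2l1 (1.53 ± 0.11) higher and Bcl2l11 (−1.04 ± 0.18) lower. Of 11 recirculating Treg genes, 2 were higher (4 adjusted over the list alone), Lgals1 (1.24 ± 0.20) and Rora, whose log2 fold change of 0.94 ± 0.23 lost its call without FOXP3lo replicate 40, 42 or 43 (0.80, 1.01 and 1.01) or mature Treg replicate 42 or 43 (0.89 and 0.88). Interferon-stimulated genes were lower in 8 of 58 (13 adjusted over the list alone, 27 lower and 1 higher without the Bst2+ libraries), for example Ifi213 (−1.08 ± 0.21) and Samd9l (−0.51 ± 0.10), at adjusted p = 7.99e-06, or adjusted p = 0.112 with an estimated correlation. NF-κB genes were higher in 9 of 25 (also 9 adjusted over the list alone), at adjusted p = 1.02e-06, or adjusted p = 0.0523 with an estimated correlation. In the mitochondrial encoded list no member was called (1 adjusted over the list alone), while camera gave adjusted p = 9.01e-04, adjusted p = 0.354 with an estimated correlation and 0.119 with fry. TCR-induced genes (6 higher, 5 lower of 25, 7 and 6 adjusted over the list alone) and mature single-positive genes (3 and 2 of 26, 4 and 7 adjusted over the list alone) were not called as lists. With the Bst2+ libraries left out the higher and lower members were 17 and 5 for IL-2 and STAT5, 10 and 2 for apoptosis, 4 and 1 for recirculating Treg, 12 and 1 for NF-κB genes. The numbers were 7 and 0 for mitochondrial, 10 and 8 for TCR-induced, 7 and 8 for mature single-positive, 3 and 0 for NKT and innate-like and 4 and 1 for CD8 and double-positive genes.

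In total 759 genes were called, 404 higher and 355 lower (155 and 97 by over 2-fold), 2919 without the Bst2+ libraries (1466 higher and 1453 lower), 2855 with only the compared groups fitted, and 123 in a test against a fold of 1.5. Of the genes named above, that last test no longer called Bcl2l11, Ifi213, Lgals1, Rora and Samd9l. DESeq2 called 1198. The number was 426, 418 and 432 without FOXP3lo progenitor replicate 40, 42 or 43 and 442 and 435 without mature Treg replicate 40 or 42. Camera adjusted p-values were 7.69e-20 for the Treg signature, 2.86e-06 for IL-2 and STAT5, 9.20e-04 for apoptosis and 0.00259 for recirculating Treg genes, and these 4 calls held with an estimated correlation. The apoptosis call was lost with an estimated correlation in the fit without the Bst2+ libraries (adjusted p = 0.0783). The NKT and innate-like list (2 of 9 higher, adjusted p = 0.0159) and the CD8 and double-positive list (1 of 11 higher, 3 adjusted over the list alone, adjusted p = 0.0134) gave adjusted p = 0.0763 and 0.0962 with an estimated correlation. The NKT call was also lost without FOXP3lo replicate 40 (0.0634) or 42 (0.064) or mature Treg replicate 43 (0.115). Socs2 (5.43 ± 0.91) and Scin (4.27 ± 0.67) rose, and Ggt5 (−4.30 ± 0.45), Rflnb (−4.19 ± 0.54), Appl2 (−4.01 ± 0.37) and Vipr1 (−3.03 ± 0.26) fell.

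The position of the progenitors between conventional cells and mature Tregs was measured on genes called at over 2-fold between those end points in a fit of their 6 libraries alone, scaling each library from 0% at the conventional mean to 100% at the mature Treg mean. On 784 genes higher in mature Tregs, CD25+ progenitors lay at 53.8% ± 1.21 and FOXP3lo progenitors at 60.2% ± 1.8, a difference of −6.37 percentage points (exact permutation test, two-sided p = 0.1, the smallest p that 3 against 3 libraries allow). On genes with a fold over 4 the difference turned to 1.1 points. On 752 genes lower in mature Tregs, CD25+ progenitors lay at 36.7% ± 3.41 and FOXP3lo progenitors at 62.2% ± 0.859, a difference of −25.49 points (exact p = 0.1). The Bst2+ libraries lay at 14% ± 12.8 and 35.8% ± 9.73 on these scales, the former being 21.33% without Bst2+ replicate 40. The genes were chosen on the conventional and mature Treg libraries, so only the other positions are free to vary.

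**Figure D4:**
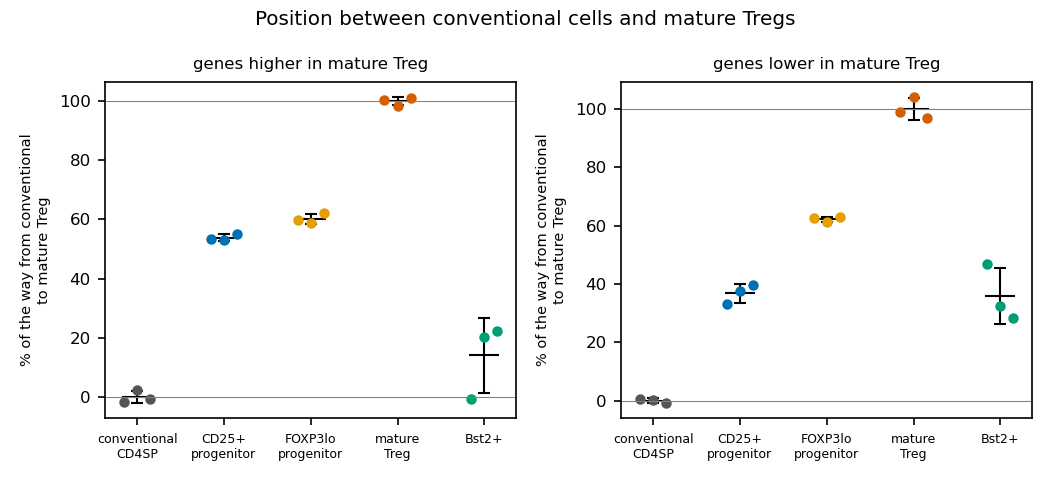
Position of each library between conventional cells (0%) and mature Tregs (100%), in percent, on 784 genes higher and 752 genes lower in mature Tregs, with points for libraries and bars for group means ± SD, n = 3. CD25+ progenitors lie at 36.7% and FOXP3lo progenitors at 62.2% on the genes that are lower in mature Tregs.

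The effect of CD25 was asked separately among FOXP3-negative gates (CD25+ progenitors over conventional cells) and FOXP3-expressing gates (mature Tregs over FOXP3lo progenitors), and the difference of these effects was tested as an interaction. Genes that mark late single-positive cells and TCR-induced genes were the lists with the most members called. Of 26 mature single-positive genes, 14 had a more positive CD25 effect among FOXP3-expressing gates and 0 a more negative one, and of 25 TCR-induced genes 13 had a more negative effect and 0 a more positive one. NF-κB genes had 6 more negative members, immature thymocyte genes 6, and IL-2 and STAT5 genes 6 more positive and 1 more negative. The Treg signature was split, with 4 more positive and 5 more negative of 26. Neb, which encodes the sarcomeric protein nebulin (ENSMUSG00000026950, chromosome 2, 52136647 to 52378474), averaged 57.8 ± 5.32 CPM in conventional cells, 15.8 ± 4.32 in CD25+ progenitors, 9.597 ± 1.05 in FOXP3lo progenitors and 69.3 ± 10.6 in mature Tregs (difference of log2 fold changes 4.73 ± 0.42, adjusted p = 4.57e-06). Rragd, a GTPase of nutrient sensing, averaged 4.44 ± 1.12, 2.56 ± 0.969, 2.65 ± 0.723 and 21.6 ± 1.84 in the same order (3.81 ± 0.54, adjusted p = 5.35e-04).

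The interaction called 378 genes, 192 higher and 186 lower (79 and 116 by over 2-fold), and 1698 without the Bst2+ libraries. Of the 378, 229 were called only for the FOXP3-negative gates, 55 only for the FOXP3-expressing gates, 59 for both in the same direction, 24 for both in opposite directions and 11 for neither. DESeq2 called 652 and a test against a fold of 1.5 called 101. The number fell to 246, 227 and 222 without FOXP3lo progenitor replicate 40, 42 or 43, to 249, 241 and 236 without mature Treg replicate 40, 42 or 43, to 243 and 248 without conventional replicate 42 or 43, and to 225 and 248 without CD25+ progenitor replicate 42 or 43.

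The Bst2+ gate, against the average of the 3 other gates with CD25 or FOXP3, carried transcripts of myeloid and of dividing cells and less of the TCR-induced and NF-κB genes. Its immature thymocyte and Treg signature calls were lost with an estimated correlation. Mrc1, the macrophage mannose receptor (ENSMUSG00000026712, chromosome 2, 14229392 to 14332057), averaged 198 ± 122 CPM and C1qc, a complement subunit made by macrophages, 149 ± 32.8, against at most 0.0529 and 0.130 in the 3 other gates. Mki67, the proliferation marker (ENSMUSG00000031004, chromosome 7, 135689784 to 135716361), averaged 662 ± 109.7 against 187 ± 41.5 in CD25+ progenitors, 62.5 ± 2.41 in FOXP3lo progenitors and 67.9 ± 16.9 in mature Tregs (2.84 ± 0.13, adjusted p = 1.10e-10). Dntt averaged 504 ± 151 (5.13 ± 0.18, adjusted p = 8.44e-12) and Rag1 397 ± 119 (5.83 ± 0.32, adjusted p = 1.14e-09). Ikzf2 averaged 217 ± 62.1 (−2.09 ± 0.13, adjusted p = 4.24e-09).

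Of 15 tested dendritic cell and macrophage genes, 15 were higher in the Bst2+ libraries (15 adjusted over the list alone), with a median log2 fold change of 8.31, or 8.16 with members at 0 at their bound. Lyz2, Csf1r and Cd74 reached 123, 77.1 and 117 CPM. Proliferation genes were higher in 29 of 29 (also 29 adjusted over the list alone, median 2.48), with Top2a at 382 ± 66.5 CPM and Birc5 at 41.4 ± 4.63. Gamma-delta genes were higher in 9 of 9 (also 9 adjusted over the list alone, median 5.35), with Trgc2 at 65.1 ± 29.4 CPM, and 7 of 11 CD8 and double-positive genes (7 adjusted over the list alone). TCR-induced genes were lower in 19 of 25 (also 19 adjusted over the list alone), with Nr4a3 (−1.38 ± 0.08) and Cd5, an inhibitory co-receptor tuned by TCR signal strength (−1.03 ± 0.08). NF-κB genes were lower in 19 of 25 (20 adjusted over the list alone), with Nfkb2 (−1.42 ± 0.10) and Tnfrsf9 (−2.28 ± 0.15). In the Treg signature 16 of 26 were lower and 3 higher (the same adjusted over the list alone). Tnfrsf1b was among the lower ones (−1.69 ± 0.11). The list had adjusted p = 5.92e-04, or adjusted p = 0.0763 with an estimated correlation.

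Several further lists were called in the Bst2+ gate only with the preset correlation. Immature thymocyte genes (14 higher, 3 lower of 25) gave adjusted p = 0.0763 with an estimated correlation, IL-2 and STAT5 genes (3 and 15 of 24) 0.0846, mature single-positive genes (1 and 14 of 26) 0.0956 and interferon-stimulated genes (3 and 24 of 58) 0.359. The interferon call was also lost without Bst2+ replicate 42 (0.0845). The direction of the interferon and mature single-positive lists depended on the gates averaged. In this gate mean log2 CPM over the interferon list was 5.14 to 5.36, against 4.71 to 4.93 in CD25+ progenitors. For mature single-positive genes it was 6.02 to 6.39 against 5.54 to 5.63, so both lists lay above CD25+ progenitors. NKT and innate-like genes (5 and 1 of 9) gave adjusted p = 0.0692 with an estimated correlation and lost the call without Bst2+ replicate 43 (0.0521), with Tyrobp and Fcer1g, signalling adaptors also expressed by myeloid cells, at 27.9 and 43.2 CPM. Mitochondrial encoded genes (12 higher of 13) gave 0.1301 and B cell genes (5 of 7) 0.163, with Ighm at 409 ± 357 CPM. Adjusted over the list alone, the higher and lower members were 16 and 3 for immature, 4 and 25 for interferon, and unchanged for the other 5 lists. Preset camera adjusted p-values were 7.79e-05 for immature, 0.0118 for IL-2 and STAT5, 0.00183 for mature single-positive, 0.0158 for interferon, 0.0123 for NKT, 3.29e-08 for mitochondrial and 0.00486 for B cell genes.

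The Bst2+ comparison called 6286 genes, 3099 higher and 3187 lower (1783 and 1503 by over 2-fold). The count may be too high, given the spread among the Bst2+ libraries. Against mature Tregs alone it called 5276 and against conventional cells 4669. A test against a fold of 1.5 called 2795 and no longer Bst2. The camera test gave adjusted p-values of 9.33e-17 for dendritic cell and macrophage, 1.42e-22 for proliferation, 8.37e-08 for gamma-delta, 6.73e-04 for CD8 and double-positive, 3.43e-07 for TCR-induced and 2.63e-08 for NF-κB genes, and these 6 calls held with an estimated correlation. Vcam1, an adhesion receptor of macrophages and stroma (ENSMUSG00000027962, chromosome 3, 116109949 to 116129688), averaged 314 ± 137 CPM against at most 0.0278 in the other 3 gates. Among genes that fell were C1ql3 (a ratio of 299 from its low count, 95% counting interval 53.5 to 11810), Kcnip2 (−6.52 ± 0.61), Plagl1 (−6.24 ± 0.74) and Prr5l (−5.37 ± 0.53).

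Lists of other cell types had members higher outside the Bst2+ gate too, the gamma-delta and CD8 lists in CD25+ progenitors being given above. NKT and innate-like genes were higher than in conventional cells in 3 of 9 cases in CD25+ progenitors (adjusted p = 0.0601) and in 4 in mature Tregs (adjusted p = 0.08405), where 3 of 7 plasmacytoid dendritic cell genes were also higher (adjusted p = 0.341). In CD25+ progenitors against conventional cells, of the B cell list 0 of 7 tested genes were higher, of the plasmacytoid dendritic cell list 2 of 7, of the dendritic cell and macrophage list 1 of 15 (Cd74, 1.70 ± 0.22) and of the thymic epithelial and stromal list 2 of 6, with 2 lower, none of these lists being called. In FOXP3lo progenitors and mature Tregs the dendritic cell and macrophage list had 0 members called higher against conventional cells. In the Bst2+ gate the stromal list had 3 higher and 2 lower of 6 (adjusted p = 0.186), the plasmacytoid list 2 and 3 of 7 (adjusted p = 0.901) and the recirculating Treg list 6 and 1 of 11 (adjusted p = 0.0796). Only 1 erythroid gene, Car2, was expressed enough to be tested, which left that list without a test. Dissociation and immediate early genes were called in mature Tregs against conventional cells (4 higher, 1 lower of 17, adjusted p = 0.0281) and against CD25+ progenitors (7 and 3, adjusted p = 0.03198), with Jun at 91.4 ± 29.9 CPM against 22.1 ± 8.37 and 12.03 ± 0.856. Both calls were lost with an estimated correlation (adjusted p = 0.163 and 0.169) and without mature Treg replicate 42 (0.11 and 0.0992), the former also without conventional replicate 40 (0.0548) and the latter without CD25+ replicate 40 (0.11). Mitochondrial encoded genes gave adjusted p = 0.0213 in mature Tregs against conventional cells, or adjusted p = 0.5397 with an estimated correlation, with 0.186 by fry, and 0.0509 and 0.0852 without conventional or mature Treg replicate 40. Across the 147 list tests 73 were called, and in each of these the median, the mean and the test had the same sign. Signs differed only for lists that were not called. Examples are immature thymocyte genes in CD25+ progenitors against conventional cells (median −0.16, mean 0.74) and the Treg signature between the progenitors (median 0.05, mean −0.05). They also differed for proliferation genes in CD25+ progenitors against conventional cells, for effector helper and gamma-delta genes in FOXP3lo progenitors against conventional cells, for CD8 and double-positive genes in mature Tregs against conventional cells, for apoptosis and recirculating Treg genes in mature Tregs against CD25+ progenitors, for immature and TCR-induced genes in mature Tregs against FOXP3lo progenitors and for chemokine genes in the Bst2+ gate. The other cases were lists of B cells, plasmacytoid dendritic cells, dendritic cells and macrophages, and stroma.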

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

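The tests of a macrophage list with its dropped members, of a lower T cell share, of RNA quality and of double-positive thymocytes were chosen only after the results were seen.

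The effect of CD25 differed between FOXP3-negative and FOXP3-expressing gates for 378 genes by the interaction test. Of 100 splits of the same libraries, the real one called the most genes and the highest other called 150. Other splits mix the gates, so gate differences enter the spread within groups and the separate effects of CD25 and FOXP3 are lost. The splits therefore cannot tell whether chance gave this count. Differences of log2 fold changes were 4.81 for Acvr1c, 4.73 for Neb, 3.81 for Rragd and 3.67 for Rap1gap2, and −8.96 for Gfra1, −5.79 for Wnt3, −5.77 for Epb41l4b and −4.81 for Tns3. Gfra1 had no count in conventional cells and Wnt3 1, so their fitted values depend on the prior count. With conventional cells at a floor of 3 counts over the group the difference for Gfra1 was −6.16. Neb and Rragd kept their calls without any one of the libraries. Acvr1c lost its call without each library of the 4 gates except FOXP3lo replicate 40 (values 4.43 to 5.29), Gfra1 without each except FOXP3lo replicate 40 and mature Treg replicate 43 (−9.15 to −8.46), and Wnt3 (−7.54 to −5.16) and Rap1gap2 (3.44 to 3.93) without each. Epb41l4b lost it without conventional replicate 40 (−5.41) or FOXP3lo replicate 43 (−4.57), and Tns3 without FOXP3lo replicate 42 (−4.58). FOXP3 level also differs between the FOXP3lo and mature gates, so this difference cannot be assigned to CD25 alone.

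The 6 pairwise comparisons allow 10 splits each, too few for a share under 0.05. The real values were 1871, 1400, 1957, 3069, 2096 and 759 called genes in the order of the report, and the highest other split called 0 in each. For Bst2+ cells 1 of 100 splits, the real one, called as many as 6286 genes and the highest other called 5. Here and in the 6 pairs, other splits mix the gates and so put gate differences into the spread within groups. Chance therefore cannot be excluded by these splits.

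Macrophage transcripts were higher in the Bst2+ libraries, though the gate required the TCR beta chain and CD4. A further macrophage list was written after the first results were seen, from genes outside the earlier lists. Of its 20 genes, 19 had a symbol and 16 passed the filter on low counts. Of the 16, 15 were higher, and with the 3 dropped genes added back 18 of 19, which is consistent with RNA from macrophages. Of the 16, 12 were under 1 CPM in the other 12 libraries and so may have passed the filter mostly through the Bst2+ libraries. Of 2963 other tested genes under that level 22.75% were higher, but these may have passed through another gate. That share cannot show whether the filter left the 15 of 16 open. The 18 of 19 covers each member with a symbol, whether or not it passed the filter. A fit with no filter gave 17, which decides nothing as it takes no account of the spread of single genes. In the Bst2+ libraries Mrc1 reached 198.1 CPM, C1qc 149.4 and Lyz2 122.8, with 11 of the 15 members of the first list under 1 CPM in the other 12 libraries. A lower share of T cell RNA that raised all other cell types alike was examined by list medians. The medians of the macrophage, B cell, stromal and plasmacytoid lists (8.16, 3.69, 2.21 and −0.17) lay 8.33 log2 units apart. The B cell, stromal and plasmacytoid lists had only 7, 6 and 7 tested genes. The macrophage members under 1 CPM elsewhere may have passed the filter mostly through the Bst2+ libraries, which by itself favours a high median. The distance between medians therefore cannot decide about such a share. A T cell share lowered by macrophage RNA itself is not addressed by these medians. For a loss of RNA quality, the lower quartile of the macrophage members' log2 fold changes was 4.84. The same limit of the filter holds for this value, so it cannot decide about RNA quality. Macrophages or doublets that passed the gate and expression by the sorted cells themselves also stay open. Pan T cell genes had 4 members higher and 4 lower of 12 (median −0.07), and the 1 tested neutrophil gene was not called (0.71).

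Some immature thymocyte and gamma-delta transcripts were higher in CD25+ progenitors than in conventional cells: 8 of 25 immature genes were higher and 6 lower, a list that was not called (adjusted p = 0.375), and 5 of 9 gamma-delta genes were higher, a call lost with an estimated correlation (adjusted p = 0.0692). RNA from CD25+ double-negative thymocytes may contribute: 5 of 11 tested double-negative genes were higher (Kit, Bcl11a, Hes1, Erg and Notch3) and Dtx1 lower, median 3.52, at adjusted p = 0.161 with an estimated correlation, which lies between the outcomes set for and against. Of these 5 genes Kit (4.05), Bcl11a (no count in conventional cells) and Notch3 (1.53) were also higher in mature Tregs than in conventional cells, and Kit (2.73) in FOXP3lo progenitors, so they do not mark double-negative cells alone. The gate required the TCR beta chain and CD4, which those cells lack. Double-positive thymocytes cannot be told apart either: the median over 5 genes was 0.55, with Aqp11 and Endou higher and Cd8a (0.09) and Cd8b1 (−0.43) not called. Per the labels, CD8-positive cells were depleted before the sort and the gate excluded CD8, which double-positive cells carry. Recently selected cells that keep such transcripts were not tested.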

How the results depend on the processing

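The fit without the Bst2+ libraries was chosen only after the results were seen. Called genes without them numbered 4534, 3925, 4756, 6187, 5114 and 2919 for the 6 pairwise comparisons in the order of the report, and 4623, 4459, 4418, 6409, 4687 and 2855 with only the groups compared, or 1698 for the interaction. Without the Bst2+ libraries the biological coefficient of variation was 0.184 in place of 0.42. A test against a fold of 1.5 called 464, 336, 628, 946, 510, 123, 2795 (Bst2+) and 101 (interaction), which its stricter question requires. DESeq2 called 1198 for mature Tregs against FOXP3lo progenitors and 652 for the interaction, and the cause was not tested.

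Leaving out 1 library gave 812 to 1035 called genes for FOXP3lo progenitors against conventional cells, 418 to 519 for mature Tregs against FOXP3lo progenitors and 222 to 270 for the interaction, with fewer libraries in each fit. The replicate block gave 1762, 1307, 1851, 2929, 2019, 710, 5799 and 352, none over 1.5 times from the unblocked count. It ended the calls of 10 named genes and no list call. Other scalings shifted the median of all genes by at most 0.05 on the log2 scale.

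The estimated correlation left 47 of 73 list calls, fry called 94 tests, and leaving out 1 library 70 to 75. For the position on genes higher in mature Tregs, a fold over 4 turned the difference from −6.37 to 1.10, and the cause was not tested. Other settings gave −7.10 to −5.37 there, and −26.9 to −23.59 on genes lower in mature Tregs.

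Besides that position, reversals were limited to gate genes without a call. Cd8a in CD25+ progenitors against conventional cells ranged from −0.21 to 0.62 without 1 library, and Bst2 from −0.19 to 0.06, with 0.02 under the replicate block. Bst2 in mature Tregs ranged from −0.10 to 0.23 against conventional cells and from −0.08 to 0.27 against CD25+ progenitors. Cd4 between the progenitors was −0.00 with upper quartile factors and −0.03 to 0.05 without 1 library. Trbc2 ranged from −0.09 to 0.03 in mature Tregs against CD25+ progenitors and from −0.06 to 0.27 in Bst2+ cells, and Cd4 in Bst2+ cells from −0.26 to 0.07. The cause was not tested. Among the named genes, calls were lost in 107 cases against a fold of 1.5, in 23 with limma-voom and in 0 with DESeq2. The fit with no filter on low counts had infinite prior degrees of freedom, so its calls take no account of the spread of single genes. A 2-fold change was often missed in the simulated counts, at the depth of these libraries and with 1 spread per gene pooled over all of them. The spread within single gates differs from the pooled one, so recovery in the real comparisons may differ. Depth was not varied, so its share in this was not tested.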

Other observations

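Both list tests of this part were chosen only after the results were seen. The ribosome biogenesis list was written after Utp20, which is not a member, was seen to be higher in CD25+ progenitors, and the values of its members had not been looked at. CD25+ progenitors may carry a larger ribosome biogenesis program: of 20 such genes 18 were higher than in FOXP3lo progenitors (median 1.19, adjusted p = 0.00322 with an estimated correlation, limma's camera). Among its members were Ncl, which encodes nucleolin, at 2121 CPM against 896.4 in FOXP3lo progenitors, and Npm1 at 995.9 against 435.5. Against conventional cells 13 were higher (median 0.61), while in FOXP3lo progenitors 12 were lower (median −0.48). Endoplasmic reticulum chaperones had 10 members higher and 1 lower of 14 (median 0.64), with an adjusted p of 0.0551 with an estimated correlation, which leaves that set open.

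Pan T cell genes were lower than in conventional cells in 9 of 12 cases in CD25+ progenitors (median −0.47), in 3 in FOXP3lo progenitors (median −0.11, Cd247, Lat and Thy1) and in 10 in mature Tregs (median −0.55), where Cd2 was higher (0.28, adjusted p = 0.0389). An unnamed gene (ENSMUSG00000097971, chromosome 17, 39843013 to 39846341) took 0.658% of the counts in conventional cells and 2.52%, 2.1%, 2.38% and 1.68% in CD25+ progenitors, FOXP3lo progenitors, mature Tregs and Bst2+ cells. The unnamed gene beside it (ENSMUSG00000098178, chromosome 17, 39846958 to 39848788) took 1.24%, 1.54%, 1.43%, 1.53% and 0.696% in the same order. Neither was identified, so whether the difference reflects expression of a gene was not tested.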
